A study of Mus musculus with 27 samples.

How the data were processed

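The deposited files held counts per gene made by the authors, 1 table for the minocycline experiment and 1 for the enrichment experiment. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned with STAR 2.6.1b to the mouse genome (mm10/GRCm38), handled with Picard 2.17.1, counted with featureCounts 1.5.3, and compared with DESeq2 1.24.0. The notes do not state the annotation release, the strand setting of the counting step, or whether duplicate reads were removed. The totals per library ran from 7.87 M to 15.3 M counts in the minocycline table and from 19.5 M to 23.9 M in the enrichment table. Every value reported here starts from those counts, and no reads were realigned.

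Gene identifiers were matched to symbols and positions in the GENCODE M21 annotation of GRCm38. A symbol was found for 53326 of 53412 identifiers in the minocycline table and for 55154 of 55421 in the enrichment table. Genes were kept by the filterByExpr function of edgeR on the groups (minimum count 10, minimum total count 15), which left 14579 and 15921 genes. Libraries were scaled by TMM. Differences were tested with the edgeR quasi-likelihood F-test (estimateDisp and glmQLFit with robust estimation), with 1 mean per group over both regions of an experiment and no covariate. The tables were never fitted together. P-values were adjusted by Benjamini-Hochberg over all tested genes of a contrast, and a gene was called changed at an adjusted p under 0.05.

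The contrasts were CUMS against NAIVE, CUMS_M against CUMS, CUMS_M against NAIVE and EE against VEH within each region, HC against PFC averaged over treatments with equal weight, and the difference of each main treatment contrast between regions. The 32 gene lists were fixed before the data were examined and tested with camera from limma on log2 CPM (prior count 2). Camera was run with its preset correlation between genes of 0.01 and again with a correlation estimated from the data, and list p-values were adjusted over the lists of a contrast. Members past the threshold were counted over all tested genes and again with p-values adjusted over the list alone.

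The genes named in the text followed a rule written beforehand. Per contrast it takes, among genes with an adjusted p under 0.05 and a regular symbol whose groups do not overlap, the 10 largest rises and the 10 largest falls. It adds up to 4 passing members of each list by smallest p, and Cx3cr1, P2ry12, Tmem119, Itgam, Il1b, Tnf, Fkbp5 and Bdnf in every contrast. Where fewer than 5 genes pass it takes the 5 of smallest p, and for a list that passes camera without a passing member it takes the 2 members of smallest p. Bdnf did not pass the count filter in either table. Genes added to this rule are named as such where they appear, and some genes that the rule names are not reported here.

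Values per group are mean CPM (counts divided by the effective library size and scaled) with the SD between libraries, and changes are log2 fold changes with the standard error of the fit. A fold against a group with 0 counts was computed against a floor of 3 counts over the whole group and is given as a lower bound. The floors cover counting error only, and the 95% intervals of list medians are bootstrap intervals over the members. For each gene the share of its exon bases that other annotated genes on the same strand also cover was computed from the annotation.

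The fit was tested on simulated data made from the real counts of 3 contrasts. In each, 100 genes were changed 2-fold and another 100 genes 4-fold in the same simulation, beside a small list raised 2-fold. For PFC CUMS against NAIVE edgeR recovered 41 of the 100 genes at a 2-fold change and 76 at a 4-fold change. The recovered numbers were 50 and 79 for HC CUMS_M against CUMS, and 46 and 76 for HC EE against VEH. None of the recovered genes had the wrong direction (0 in each case), and 4, 7 and 4 unchanged genes were called.

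The alternatives tried were the size factors of DESeq2, no filter on low counts, the DESeq2 Wald test, the replicate number as a block, a covariate of non-microglial markers, a fit of only the groups compared, and leaving out each library in turn. Alternatives added after the data were seen are listed where the dependence on the processing is described. Every comparison of groups of at least 3 libraries was repeated on other splits of the same libraries. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used. The labels do not say that the regions came from the same animals, so no paired fit was used as the first choice. In the PFC of the enrichment table the libraries with equal number in EE and VEH deviated together from their group means (r = 0.359, 0.198 and 0.208). These numbers met the bound of 0.1 for every pair and were treated as possible pairs, which comes from the data and not from the labels. Deviations within a group of 3 sum to 0, so the r values depend on each other. PFC EE 1 and PFC VEH 1 both scored high on the first principal component (69.9 and 48.7), and such a match of 1 pair raises the others. The r values therefore cannot decide whether the samples were paired. The other comparisons did not meet that bound, and the experiments' groups were not pooled.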

Results

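The data are RNA-seq counts from CD11b+ cells sorted out of the prefrontal cortex (PFC) and the hippocampus (HC) of C57BL/6 mice. CD11b, encoded by Itgam, is a surface integrin carried by microglia and by other myeloid cells. Chronic unpredictable mild stress (CUMS) is a protocol of changing mild stressors used as a model of depression, minocycline is a tetracycline antibiotic that dampens microglial activation, and environmental enrichment (EE) is housing with more space and objects. The minocycline experiment had 15 libraries: NAIVE (2 in PFC, 2 in HC), CUMS (2 in PFC, 3 in HC) and CUMS with minocycline (CUMS_M, 3 in PFC, 3 in HC). The enrichment experiment had 12 libraries, 3 per region of CUMS with vehicle (VEH) and 3 per region of CUMS with EE. Totals ran from 7.87 M to 8.20 M counts in PFC NAIVE, 10.6 to 12.4 in PFC CUMS, 8.62 to 11.2 in PFC CUMS_M, 11.8 to 12.8 in HC NAIVE, 13.2 to 14.5 in HC CUMS and 13.3 to 15.3 in HC CUMS_M. In the enrichment table they ran from 19.5 M to 23.9 M counts. The labels do not say that the replicates are separate animals, so the p-values measure the spread between samples. No batch of dissociation, sorting or sequencing is given either, so effects of handling and of treatment cannot be separated.

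Gene lists are given with the median log2 fold change of their members, the camera p-value of limma at the preset correlation, and the p-value with an estimated correlation. Only the list of glucocorticoid-responsive genes passed with an estimated correlation, in HC CUMS against NAIVE, in HC CUMS_M against CUMS and in the difference of the latter between regions. Each of these contrasts uses the same HC CUMS libraries, so a shift of that group alone could give all of these passes, which are not independent. In HC CUMS_M against NAIVE, which leaves those libraries out, 0 lists passed with an estimated correlation. At the preset correlation random regroupings of the same 6 libraries gave a median of 11 called lists for HC CUMS_M and CUMS, 15 for PFC EE and VEH, and 10 for HC EE and VEH. The other list calls are therefore given as measured shifts of whole groups of genes.

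**Figure D1:**
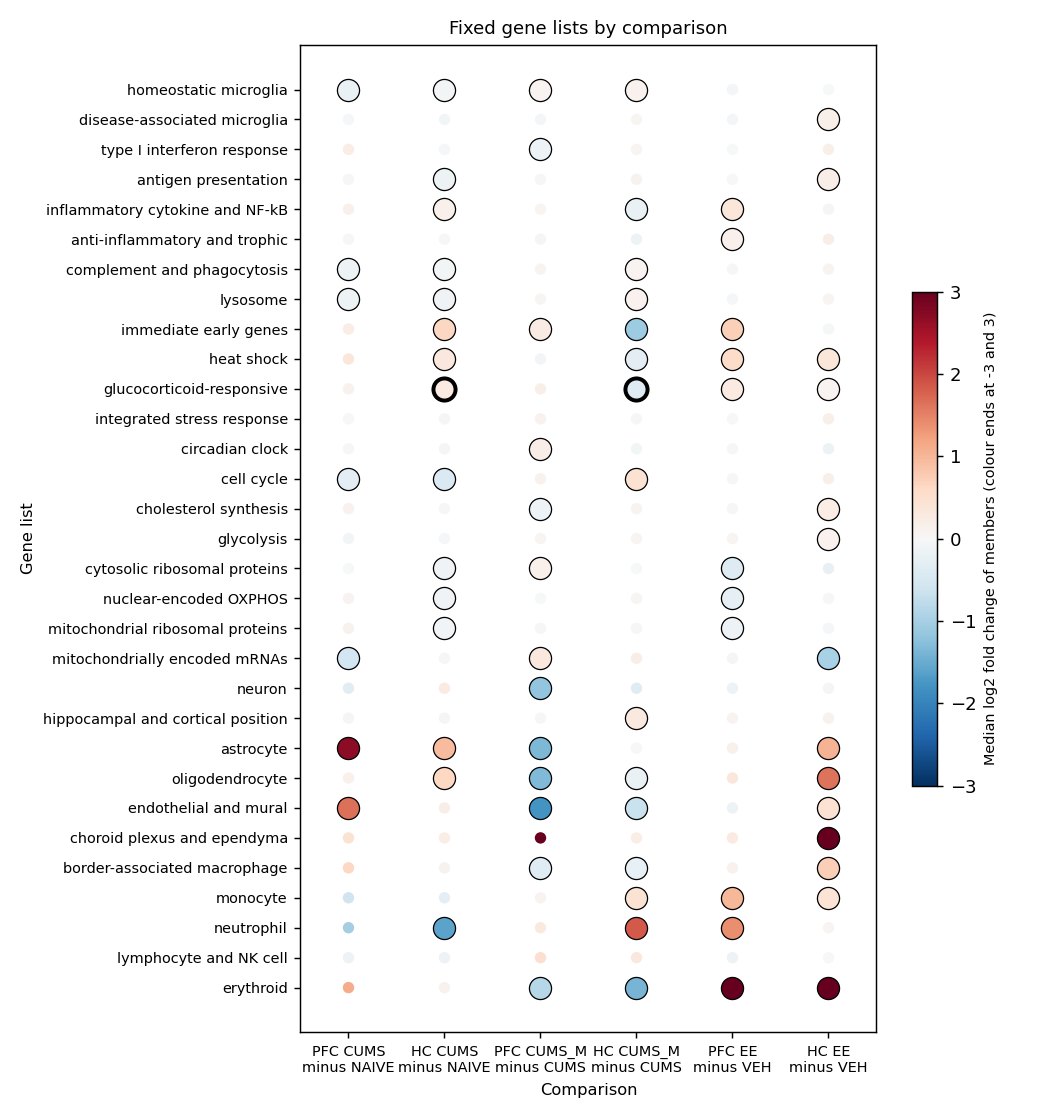
Every fixed list except the sex-linked one (vertical axis) in 6 treatment contrasts (horizontal axis), with colour for the median log2 fold change of the members, limited to 3 in either direction, a black ring for a camera adjusted p under 0.05, and a thick ring for a list that also passed with an estimated correlation. The thick rings are the glucocorticoid-responsive list in HC CUMS against NAIVE (0.27) and in HC CUMS_M against CUMS (-0.38).

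The first question was what CUMS changed in CD11b+ cells of the PFC. Genes of astrocytes, the glial cells that take up glutamate, rose in PFC CUMS against PFC NAIVE (n = 2 and 2). Aldh1l1, a folate enzyme used as an astrocyte marker, rose from 1.005 ± 0.497 to 9.73 ± 0.51 CPM (counts scaled by library size, mean ± SD) (log2 fold change 3.25 ± 0.40, edgeR adjusted p = 0.00155). Ntsr2, an astrocytic neurotensin receptor, rose from 1.34 ± 0.325 to 14.5 ± 0.0619 (3.43 ± 0.48, edgeR adjusted p = 0.00172). Gja1, the gap junction protein connexin 43 of astrocytes, rose by 2.87 ± 0.46 (edgeR adjusted p = 0.0144) and Aldoc, a brain aldolase, by 2.99 ± 0.45 (0.0154). Gja1 missed the threshold without PFC NAIVE 1 (0.124), PFC CUMS 2 (0.0817), PFC CUMS 1 (0.0534) or PFC NAIVE 2 (0.0506), and Aldoc without PFC NAIVE 1 (0.136), PFC CUMS 2 (0.0997) or PFC CUMS 1 (0.0660), while Aldh1l1 and Ntsr2 passed in every leave-out. In the astrocyte list 7 of 12 members rose, and 12 did when adjusted over the list alone, with a median of 2.67 (camera adjusted p = 2.28e-14, adjusted p = 0.331 with an estimated correlation). The lowest median over the alternative fits was 1.36, against 2.37 to 2.65 over the leave-outs. The mean level of the astrocyte list was 2.15 and 2.50 log2 CPM in the NAIVE libraries and 4.72 and 4.78 in the CUMS libraries.

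Genes of endothelial and mural cells, which line and wrap blood vessels, rose beside them. Ly6c1, an endothelial surface protein, rose from 0.881 ± 0.322 to 10.6 ± 2.46 CPM (3.56 ± 0.55, edgeR adjusted p = 0.00458). Cldn5, a claudin of the blood-brain barrier, rose by 2.06 ± 0.41 (edgeR adjusted p = 0.0206) and Flt1, a VEGF receptor, by 2.19 ± 0.43 (0.045). Ly6c1 missed the threshold without PFC NAIVE 1 (0.0927), Flt1 without PFC CUMS 1 (0.142), PFC CUMS 2 (0.284) or PFC NAIVE 1 (0.250), and Cldn5 without any one of the 4 libraries (0.0516 to 0.210). In this list 3 of 12 members rose, 6 when adjusted over the list alone, with a median of 1.66 (camera adjusted p = 3.86e-06, adjusted p = 0.89 with an estimated correlation). Leaving out PFC NAIVE 1 moved that median to 0.99, and leaving out PFC NAIVE 2 moved it to 2.77. With a score of non-microglial markers, which contains these members, as a covariate it was 0.80 (camera adjusted p = 0.135). Emcn, an endothelial sialomucin, had 0 counts in PFC NAIVE and was at least 15.5-fold higher in PFC CUMS (edgeR adjusted p = 0.0156). Spon1, a secreted matrix protein, was at least 15.3-fold higher (0.00937, and 0.0644 without PFC NAIVE 1) and Timp4, a metalloproteinase inhibitor, at least 14.2-fold higher (0.0393). The same kind of bound was 12.8 for the BMP receptor Bmpr1b, 11.9 for the Notch ligand Jag1 and 10.6 for the sulfate donor enzyme Papss2. Emcn, Spon1, Timp4, Bmpr1b, Jag1 and Papss2 are not in the endothelial and mural list, and which cells their RNA came from was not tested. Emcn, Bmpr1b, Jag1 and Papss2 missed the threshold without PFC CUMS 1, PFC CUMS 2 or PFC NAIVE 1 (0.0529 to 0.109), and Timp4 without any one of the 4 libraries (0.0806 to 0.192).

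Few genes fell in PFC CUMS. Actn1, an actin crosslinker, fell by 0.69 ± 0.15 (log2, edgeR adjusted p = 0.0325), and Il6st, the signal-transducing IL-6 receptor subunit, fell by 0.56 ± 0.11 (0.0185), from 788 ± 9.46 to 535 ± 63 CPM. Marcks, a membrane-bound protein of motile microglia, fell by 0.46 ± 0.10 (edgeR adjusted p = 0.024), from 1340 ± 93.3 to 974 ± 22.8. Some falls were in genes whose exons overlap other genes, so their source is uncertain, as for CT010467.1 (37.4% of its exon bases shared) and the protocadherin Pcdhgb2 (43.4%). Mfge8, a bridging protein for phagocytosis of dying cells, rose from 36.8 ± 1.97 to 72.2 ± 12 (0.97 ± 0.20, edgeR adjusted p = 0.0185). The calls ended for Actn1 and Marcks without any one of the 4 libraries (0.0763 to 0.295). They ended for Il6st without PFC CUMS 1 (0.0529), PFC CUMS 2 (0.375) or PFC NAIVE 1 (0.107), and for Mfge8 without PFC CUMS 2 (0.273), PFC NAIVE 1 (0.111) or PFC NAIVE 2 (0.0695).

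Microglial identity genes were lower by small amounts without passing the test. Their list had a median of -0.19 with 4 of 20 members above 0 (camera adjusted p = 0.000403, adjusted p = 0.89 with an estimated correlation), and without PFC NAIVE 1 the camera adjusted p was 0.0587. Cx3cr1, the fractalkine receptor, gave -0.28 ± 0.09 (edgeR adjusted p = 0.172) and P2ry12, a purinergic receptor for process movement, gave -0.33 ± 0.14 (0.296). Il1b, the cytokine IL-1β, gave 0.55 ± 0.29 (0.423) and Fkbp5, a chaperone of the glucocorticoid receptor, gave -0.11 (0.794). The lysosome list had a median of -0.15 (camera adjusted p = 0.00151, adjusted p = 0.89 with an estimated correlation, and -0.0795 with camera 0.148 without PFC NAIVE 1), and its member of smallest p was the cholesterol transporter Npc1 at -0.40 (0.114). The neuron list had a median of -0.34, a mean of 0.19 and a camera adjusted p of 0.652, although Stmn2, a neuronal tubulin regulator, was at least 9.51-fold higher (edgeR adjusted p = 0.0486, and 0.0655 to 0.227 without any one of the 4 libraries).

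With edgeR 108 genes rose and 11 fell in PFC CUMS, 1992 genes had an unadjusted p under 0.05, and DESeq2 called 348. Leaving out 1 library changed the count of 119 to 25 (without PFC CUMS 1), 13 (without PFC CUMS 2), 30 (without PFC NAIVE 1) and 540 (without PFC NAIVE 2). PFC NAIVE 1 had the highest score on the first principal component (91.4, with PFC CUMS_M 2 next at 55.2, and 30.5% of the variance) and the highest neuron level (2.37 log2 CPM, against 0.0044 to 1.82 in the others).

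**Figure D2:**
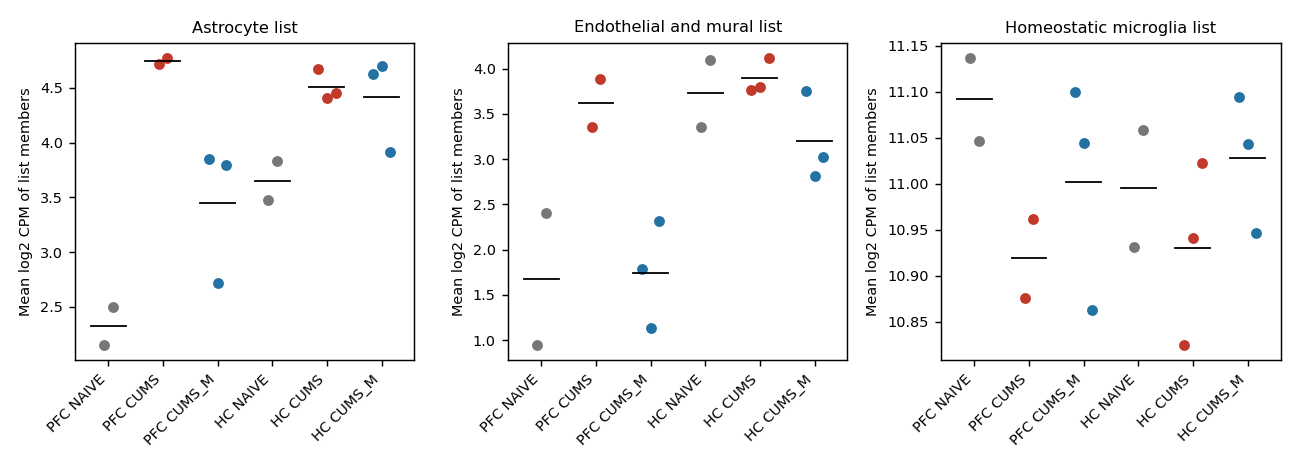
Mean log2 CPM of the members of the astrocyte, endothelial and mural, and homeostatic microglia lists (vertical axes) in each library of the 6 groups of the minocycline experiment (horizontal axis), with points for libraries and lines for group means. The astrocyte list was at 2.15 and 2.50 in PFC NAIVE, 4.72 and 4.78 in PFC CUMS, and 2.72 to 3.85 in PFC CUMS_M.

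In the HC no single gene was called for the same question. Immediate early genes, transcription factors switched on within minutes of a stimulus, were higher in HC CUMS than in HC NAIVE (n = 3 and 2), with all 22 of 22 members above 0 and a median of 0.65 (camera adjusted p = 2.76e-14, adjusted p = 0.417 with an estimated correlation). That median was 0.41 without HC CUMS 1, 1.27 without HC NAIVE 1 and 0.26 without HC NAIVE 2. Heat shock genes, chaperones of the stress response, were higher in the same contrast by a median of 0.32, with 0 members called over all genes (camera adjusted p = 0.000125, adjusted p = 0.417 with an estimated correlation, camera 0.0550 without HC CUMS 1). Klf6, a zinc finger factor of the immediate early list, was at 375 ± 99.6 CPM against 250 ± 28.2. Glucocorticoid-responsive genes, targets of the stress hormone receptor, had 17 of 18 members above 0, a median of 0.27 and 2 members past the threshold when adjusted over the list alone (camera adjusted p = 2.05e-06, adjusted p = 0.0102 with an estimated correlation). Per1, a clock gene that glucocorticoids induce directly, was at 189 ± 4.03 against 110 ± 24.8 (0.78 ± 0.14, edgeR adjusted p = 0.456). Nfkbia, the NF-kB inhibitor, was at 310 ± 79.8 against 175 ± 30.3 (0.82 ± 0.23).

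Astrocyte genes were also higher in HC CUMS, with a median of 0.95 and 7 members past the threshold when adjusted over the list alone (camera adjusted p = 9.02e-11, adjusted p = 0.356 with an estimated correlation). Slc4a4, a bicarbonate transporter of astrocytes, gave 1.41 and Ntsr2 1.16. Tril, a coreceptor of toll-like receptors made by astrocytes, was at 14.5 ± 1.95 against 5.65 ± 0.644 (1.36 ± 0.30). Neutrophil genes were lower, with 0 of 12 members above 0 and a median of -1.62 (camera adjusted p = 4.93e-06, adjusted p = 0.528 with an estimated correlation), and the median was -1.04 without HC NAIVE 2. S100a9, a calprotectin subunit of neutrophils, was at 107 ± 49.1 against 431 ± 213 CPM. The cell cycle list gave -0.42 (camera adjusted p = 6.89e-06, adjusted p = 0.417 with an estimated correlation). With edgeR 0 genes passed (smallest adjusted p = 0.456), 418 had an unadjusted p under 0.05, and DESeq2 called 1.

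The difference between regions in the effect of CUMS was tested directly. It was -1.69 for the astrocyte list (HC effect minus PFC effect, camera adjusted p = 5.74e-08, adjusted p = 0.632 with an estimated correlation) with 5 members past the threshold when adjusted over the list alone. It was -1.64 for the endothelial and mural list (camera adjusted p = 2.32e-05, adjusted p = 0.93 with an estimated correlation) and 0.47 for the immediate early genes (camera adjusted p = 0.000438, adjusted p = 0.96 with an estimated correlation). The glucocorticoid-responsive list gave 0.28 (camera adjusted p = 0.0139, adjusted p = 0.317 with an estimated correlation). With edgeR 0 single genes passed (smallest adjusted p = 0.157, with 140 passing without PFC NAIVE 2 and 2 without HC NAIVE 2), 914 had an unadjusted p under 0.05, and DESeq2 called 27.

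The next question was what minocycline changed in stressed animals, and the labels give no vehicle for the CUMS group of this experiment. In PFC CUMS_M against PFC CUMS (n = 3 and 2) Cldn5 fell from 15.3 ± 1.17 to 3.14 ± 1.42 CPM (by 2.25 ± 0.36 on the log2 scale, edgeR adjusted p = 0.041). Ptn, a heparin-binding growth factor of astrocytes and mural cells, fell from 32.2 ± 5.71 to 8.18 ± 2.63 (by 1.97 ± 0.31, edgeR adjusted p = 0.041). Plxnb1, a semaphorin receptor, fell from 19.7 ± 1.69 to 5.87 ± 2.48 (by 1.72 ± 0.27, edgeR adjusted p = 0.041). The pericyte receptor Pdgfrb was next with -2.02 (0.0819). Without 1 library the adjusted p reached 0.811 for Cldn5, 0.905 for Ptn and 0.811 for Plxnb1 (each without PFC CUMS 2). These 3 falls were the only genes called by edgeR, 808 had an unadjusted p under 0.05, and DESeq2 called 85. No gene passed (0) without PFC CUMS 1, PFC CUMS 2 or PFC CUMS_M 2, while 5 passed without PFC CUMS_M 1 (not Cldn5 at 0.124 or Plxnb1 at 0.0817) and 9 without PFC CUMS_M 3 (not Ptn at 0.0952).

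The lists of other cells went down with those genes. Astrocyte genes had 0 of 12 members above 0 and a median of -1.35, with 10 past the threshold when adjusted over the list alone (camera adjusted p = 4.05e-14, adjusted p = 0.186 with an estimated correlation). Endothelial and mural genes gave -1.80, with 1 fall over all genes and 8 when adjusted over the list alone (camera adjusted p = 4.05e-14, adjusted p = 0.186 with an estimated correlation). Oligodendrocyte genes, those of myelin-forming cells, gave -1.32 (camera adjusted p = 3.14e-08, adjusted p = 0.445 with an estimated correlation) and neuron genes -1.18 (0.000126 and 0.787). With the score of non-microglial markers as a covariate the astrocyte median was -0.11 (camera adjusted p = 0.564), and the oligodendrocyte and neuron medians turned to 1.203 (0.00103) and 0.34 (0.345). The choroid plexus list, secretory epithelium of the ventricles, had a fitted median of 4.73 and 2.37 with its members at the bound, and this came from PFC CUMS_M 3 alone (level 3.001 log2 CPM, against -1.71 to -0.64 in the other PFC libraries). Cx3cr1 gave 0.13, P2ry12 0.12, Il1b -0.34, Tnf 0.36 and Fkbp5 0.01, none of them past the threshold (edgeR adjusted p = 1 for Fkbp5).

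In HC CUMS_M against HC CUMS (n = 3 and 3) Per1 fell from 189 ± 4.03 to 94.3 ± 4.82 CPM (by 1.01 ± 0.13 on the log2 scale, edgeR adjusted p = 0.00311). Without HC CUMS_M 1 its log2 fold change was -0.96 with an adjusted p of 0.0632 in edgeR. The glucocorticoid-responsive list gave -0.38 with 3 of 18 members above 0, 1 fall over all genes and 6 when adjusted over the list alone (camera adjusted p = 5.98e-09, adjusted p = 0.00259 with an estimated correlation), and its median was -0.24 without HC CUMS 3. Immediate early genes gave -1.09 with 0 of 22 members above 0 and 20 past the threshold when adjusted over the list alone (camera adjusted p = 1.9e-29, adjusted p = 0.119 with an estimated correlation). Dusp1, a phosphatase that ends MAP kinase signalling, was at 297 ± 43.4 against 739 ± 195 CPM, and the early response gene Ier2 at 112 ± 27.6 against 262 ± 73.2.

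Inflammatory cytokine and NF-kB genes moved with them, with a median of -0.19, a mean of -0.49 and 7 members past the threshold when adjusted over the list alone (camera adjusted p = 1.02e-07, adjusted p = 0.113 with an estimated correlation). The median was -0.31 without HC CUMS_M 1. Il1b was at 17 ± 6.48 against 34.8 ± 6.33 CPM (-1.04 ± 0.24, edgeR adjusted p = 0.582, but 0.0276 without HC CUMS_M 3), Tnf, the cytokine TNF, at 16.2 ± 3.25 against 38.5 ± 11.8 (-1.25 ± 0.33, 0.725), and Nfkbia at 147 ± 14 against 310 ± 79.8 (-1.07, 0.555). Heat shock genes gave -0.33 (camera adjusted p = 1.61e-05, adjusted p = 0.275 with an estimated correlation), and -0.19 without HC CUMS 1. Plk2, a kinase of the immediate early response, was at 3.69 ± 0.211 against 9.67 ± 1.33 (edgeR adjusted p = 0.273). Cx3cr1 gave 0.22 (edgeR adjusted p = 0.956) and Fkbp5 -0.44 (0.756).

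Other groups of genes went up in HC CUMS_M against HC CUMS. Neutrophil genes had 12 of 12 members above 0 and a median of 1.85 (camera adjusted p = 4.61e-06, adjusted p = 0.423 with an estimated correlation), and 0.90 without HC CUMS_M 3, whose neutrophil level was 6.56 log2 CPM. Ngp, a granule protein of neutrophils, was at 257 ± 219 against 57.9 ± 28 CPM. Cell cycle genes gave 0.45 with 20 of 21 members above 0 (camera adjusted p = 4.61e-06, adjusted p = 0.275 with an estimated correlation), and 0.29 without HC CUMS_M 3. The proliferation marker Mki67 was at 15.3 ± 5.32 against 7.08 ± 1.04. Lists of other cells also went down. Endothelial and mural genes gave -0.66 (camera adjusted p = 2.77e-05, adjusted p = 0.42 with an estimated correlation), -0.44 without HC CUMS 3 and -1.02 without HC CUMS_M 1. Erythroid genes gave -1.39 (camera adjusted p = 0.00049, adjusted p = 0.423 with an estimated correlation), and that call ended without HC CUMS 3 (-0.65, 0.168) or HC CUMS_M 2 (-1.05, 0.0946). With edgeR 1 gene passed (Per1), 584 had an unadjusted p under 0.05, and DESeq2 called 36. The edgeR count was 5 without HC CUMS 3, 2 without HC CUMS_M 3 and 0 without HC CUMS_M 1.

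**Figure D3:**
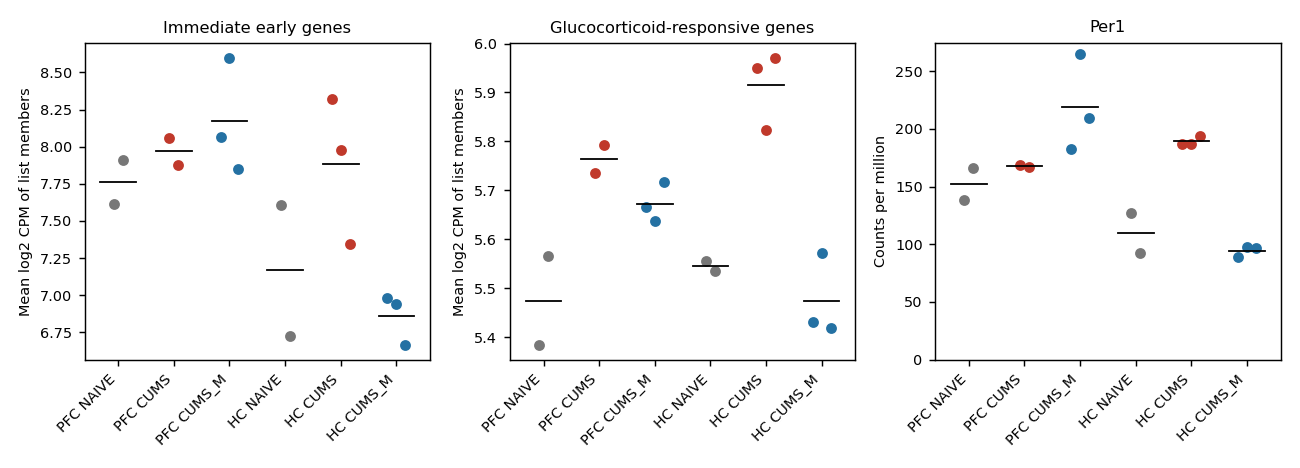
Mean log2 CPM of the immediate early and glucocorticoid-responsive lists and CPM of Per1 (vertical axes) in each library of the 6 groups of the minocycline experiment (horizontal axis), with points for libraries and lines for group means. The immediate early list was at 7.35 to 8.32 in HC CUMS and 6.66 to 6.98 in HC CUMS_M.

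The tested difference between regions in the effect of minocycline called Per1 alone (HC effect minus PFC effect -1.39 ± 0.19, edgeR adjusted p = 0.0107). In the PFC Per1 was at 219 ± 42.4 CPM in CUMS_M against 168 ± 1.45 in CUMS (0.38 ± 0.14, edgeR adjusted p = 0.604). The call ended without HC CUMS 3 (0.0575), HC CUMS_M 1 (0.0631), PFC CUMS 1 (0.197) or PFC CUMS 2 (0.151). The glucocorticoid-responsive list differed by -0.32 (camera adjusted p = 3.6e-07, adjusted p = 0.00716 with an estimated correlation) with 6 members past the threshold when adjusted over the list alone. Immediate early genes differed by -1.54 with 17 such members (camera adjusted p = 2.39e-22, adjusted p = 0.229 with an estimated correlation), and inflammatory cytokine and NF-kB genes by -0.49 (2.22e-07 and 0.129). The astrocyte list differed by 1.243 (camera adjusted p = 1.21e-09, adjusted p = 0.229 with an estimated correlation). With edgeR 1 gene was called, 506 had an unadjusted p under 0.05, and DESeq2 called 2.

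Treated and naive animals were compared to see how far the CUMS_M samples stood from NAIVE. In PFC CUMS_M against PFC NAIVE (n = 3 and 2) Aldh1l1 was higher, at 5.72 ± 0.739 against 1.005 ± 0.497 CPM (2.48 ± 0.39, edgeR adjusted p = 0.017). Spon1 was at least 10.8-fold higher (edgeR adjusted p = 0.0407). Orai1, a store-operated calcium channel, fell from 230 ± 11.6 to 158 ± 12 (by 0.54 ± 0.10, edgeR adjusted p = 0.0475), and Det1, a ubiquitin ligase subunit, fell by 1.07 ± 0.20 (0.0384). Without PFC NAIVE 1 none of these passed (0.182 for Aldh1l1, 0.228 for Spon1, 0.254 for Orai1 and 0.276 for Det1). Spon1 also missed the threshold without PFC CUMS_M 1 (0.0638) or 3 (0.118), and Orai1 and Det1 without any one CUMS_M library (0.0557 to 0.138). The astrocyte list gave 1.29 with 1 rise over all genes and 7 when adjusted over the list alone (camera adjusted p = 4.56e-05, adjusted p = 0.891 with an estimated correlation). Other cell lists were lower, oligodendrocyte genes by -1.05 (camera adjusted p = 0.00449), neutrophil genes by -0.69 (0.0430) and monocyte genes by -0.63 (0.0364). None of these passed with an estimated correlation, and each call ended without some single CUMS_M library. With edgeR 11 genes rose and 2 fell, 2034 had an unadjusted p under 0.05, and DESeq2 called 143. The count of 13 was 0 without PFC NAIVE 1, 610 without PFC NAIVE 2, and 6, 25 and 4 without PFC CUMS_M 1, 2 and 3.

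In HC CUMS_M against HC NAIVE (n = 3 and 2) the astrocyte list gave 0.88 with 12 of 12 members above 0 and 2 past the threshold when adjusted over the list alone (camera adjusted p = 1.04e-08, adjusted p = 0.965 with an estimated correlation). Immediate early genes gave -0.38 (camera adjusted p = 0.000757, adjusted p = 0.965 with an estimated correlation), but 0.16 without HC NAIVE 1 and -0.76 without HC NAIVE 2. The call of that list ended with the replicate number as a block. Adcyap1r1, the PACAP receptor, gave 1.55 and Tril 1.21, neither past the threshold. With edgeR 0 genes passed (smallest adjusted p = 0.618), 339 had an unadjusted p under 0.05, and DESeq2 called 1.

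All 3 genes called in PFC CUMS_M against CUMS (Cldn5, Ptn and Plxnb1) were called in the opposite direction in PFC CUMS against NAIVE, a contrast that shares the CUMS libraries. Across the 14579 genes the log2 fold changes of CUMS against NAIVE and of CUMS_M against CUMS had a Pearson r of -0.330 in the PFC and -0.447 in the HC. Both contrasts share the CUMS libraries, and simulations without any effect gave -0.518 ± 0.0132 and -0.424 ± 0.0183. The covariance, which does not shrink with spread, was -0.331 in the PFC against -0.200 ± 0.00875 simulated, and -0.111 in the HC against -0.116 simulated. Genes are not independent replicates in these correlations, while the simulations drew each gene independently, so the simulated spread leaves out correlation between genes. A joint deviation of the shared CUMS libraries also makes the covariance more negative. These values therefore cannot decide whether minocycline moved the CUMS profile back towards NAIVE.

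The enrichment experiment asked what EE changed in stressed animals, and the labels do not say whether the EE group received vehicle. The region of each library is taken from its label, although the choroid plexus markers did not follow these labels in this table. In PFC EE against PFC VEH (n = 3 and 3) genes of red blood cells were higher, with 7 of 7 members above 0, all 7 past the threshold when adjusted over the list alone, and a median of 3.46 (camera adjusted p = 1.6e-18, adjusted p = 0.117 with an estimated correlation). Hba-a1, an alpha globin, was at 139 ± 100 against 11.1 ± 3.77 CPM (3.65 ± 0.57, edgeR adjusted p = 0.506). Alas2, the erythroid enzyme of heme synthesis, was at 36.3 ± 27.4 against 2.89 ± 0.646, and the beta globin Hbb-bs at 321 ± 221 against 29.1 ± 9.98.

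Immediate early genes were higher in PFC EE with a median of 0.72, 21 of 22 members above 0 and 10 past the threshold when adjusted over the list alone (camera adjusted p = 9.14e-17, adjusted p = 0.291 with an estimated correlation). Junb, an AP-1 subunit, was at 3031 ± 604 against 1820 ± 342 CPM. Inflammatory cytokine and NF-kB genes gave 0.36 with 5 such members (camera adjusted p = 1.8e-08, adjusted p = 0.233 with an estimated correlation), where Il1a, the cytokine IL-1α, was at 125 ± 29.6 against 69.9 ± 6.27 and Il1b at 81.1 ± 13.2 against 47 ± 7.83 (0.79 ± 0.18, edgeR adjusted p = 0.802). Heat shock genes gave 0.58 with 5 such members (camera adjusted p = 3.2e-08, adjusted p = 0.268 with an estimated correlation). Neutrophil genes gave 1.40 (camera adjusted p = 0.00151, adjusted p = 0.976 with an estimated correlation) but 0.20 (0.546) without PFC EE 1, which stood apart on the first principal component (69.9) and had a neutrophil level of 6.75 log2 CPM. Genes of cytosolic ribosomal proteins gave -0.38 (camera adjusted p = 0.00104, adjusted p = 0.989 with an estimated correlation) but 0.19 without PFC VEH 1 (0.000157), a camera adjusted p of 0.165 without PFC EE 2 and of 0.175 without PFC EE 3, and medians of -0.60 without PFC EE 1 and -0.69 without PFC VEH 3. Cx3cr1 gave -0.09 and Fkbp5 0.08. With edgeR 0 genes passed (smallest adjusted p = 0.506), 677 had an unadjusted p under 0.05, and DESeq2 called 17.

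**Figure D4:**
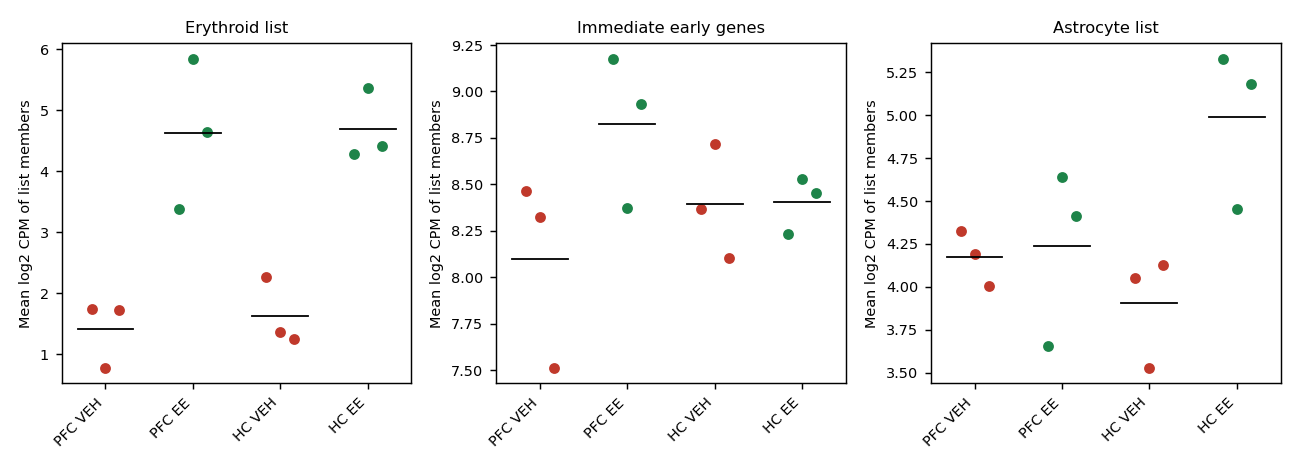
Mean log2 CPM of the erythroid, immediate early and astrocyte lists (vertical axes) in each library of the 4 groups of the enrichment experiment (horizontal axis), with points for libraries and lines for group means. The erythroid list was at 3.39 to 5.84 in PFC EE, 0.78 to 1.74 in PFC VEH, 4.28 to 5.36 in HC EE and 1.26 to 2.26 in HC VEH.

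In HC EE against HC VEH (n = 3 and 3) the erythroid list gave 3.18 with 6 members past the threshold when adjusted over the list alone (camera adjusted p = 2.12e-11, adjusted p = 0.367 with an estimated correlation), and Hbb-bs was at 311 ± 157 against 29.9 ± 6.13 CPM (3.38, edgeR adjusted p = 0.0748). Oligodendrocyte genes gave 1.64 with 12 of 12 members above 0 and 10 past the threshold when adjusted over the list alone (camera adjusted p = 2.07e-11, adjusted p = 0.367 with an estimated correlation). The lowest median of that list over the alternative fits was 0.53, against 1.45 over the leave-outs. Cldn11, a claudin of myelin, was at 21.2 ± 5.87 against 3.51 ± 0.264 (2.59 ± 0.45, edgeR adjusted p = 0.0715). Astrocyte genes gave 1.05 with 11 such members (camera adjusted p = 4.94e-10, adjusted p = 0.367 with an estimated correlation). Genes of border-associated macrophages, the macrophages of the meninges and vessels that also carry CD11b, gave 0.74 with 7 such members (camera adjusted p = 2.49e-07, adjusted p = 0.367 with an estimated correlation), where the scavenger receptor Cd163 was at 103 ± 21.8 against 54 ± 3.43 (edgeR adjusted p = 0.079). The choroid plexus list gave 3.20 (camera adjusted p = 1.43e-05, adjusted p = 0.466 with an estimated correlation), and 6.18 without HC VEH 3.

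In HC EE Fasn, the fatty acid synthase, was at 83.9 ± 4.88 against 51.8 ± 1.29 CPM in HC VEH (0.70 ± 0.11, edgeR adjusted p = 0.0603). The cholesterol synthesis list gave 0.23 with 5 members past the threshold when adjusted over the list alone (camera adjusted p = 0.000845, adjusted p = 0.466 with an estimated correlation), 0.15 without HC EE 2 and 0.37 without HC VEH 1. With the score of non-microglial markers as a covariate it was 0.0312 and the call ended (camera adjusted p = 0.830). Tyro3, a receptor kinase for dying cells, was at 6.37 ± 2.11 against 1.05 ± 0.184 (2.604 ± 0.40, edgeR adjusted p = 0.0603). Among disease-associated microglia genes (median 0.18, camera adjusted p = 0.048, adjusted p = 0.731 with an estimated correlation) the lipid carrier Apoe was at 2265 ± 471 against 1216 ± 265 (0.90 ± 0.21, edgeR adjusted p = 0.112). That list call ended without HC EE 2 (0.122), HC EE 3 (0.150) or HC VEH 2 (0.424), and with only the libraries of the region (0.0626). The median was 0.28 without HC VEH 1 and turned to -0.15 with the score as a covariate (0.308). Il1b gave 0.48 (edgeR adjusted p = 0.353), Tnf 0.02 and Cx3cr1 0.02. With edgeR 0 genes passed (smallest adjusted p = 0.0603), 1652 had an unadjusted p under 0.05, and DESeq2 called 441. Without HC EE 2 edgeR called 41.

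The tested difference between regions in the effect of EE was -0.72 for immediate early genes (adjusted p = 0.608 with an estimated correlation) and 1.28 for oligodendrocyte genes. In this contrast 13 lists passed at the preset correlation and 0 with an estimated correlation. With edgeR 0 single genes passed (smallest adjusted p = 0.998), 670 had an unadjusted p under 0.05, and DESeq2 called 0. The effects of minocycline and of EE were not correlated beyond other groupings of the libraries across the 14216 genes tested in both tables. Pearson r was -0.061 in the PFC (76 of 100 splits as large in absolute value) and -0.013 in the HC.

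The last comparison was between regions. In the minocycline experiment (HC against PFC, n = 8 and 7) genes of the choroid plexus were higher in the HC, with 7 of 10 members past the threshold, 9 when adjusted over the list alone, and a median of 5.04 (camera adjusted p = 1.57e-09, adjusted p = 0.332 with an estimated correlation). Ttr, the transthyretin secreted into cerebrospinal fluid, gave 6.98 ± 1.42 (edgeR adjusted p = 0.0258), and its call ended without HC NAIVE 1 (0.0504), HC NAIVE 2 (0.0597), PFC CUMS 1 (0.138), PFC CUMS 2 (0.113), PFC NAIVE 1 (0.0897) or PFC NAIVE 2 (0.0769). Endothelial and mural genes were also higher in the HC, 6 of them past the threshold and 8 when adjusted over the list alone, with a median of 1.12 (camera adjusted p = 2.59e-08, adjusted p = 0.332 with an estimated correlation), among them Ly6c1 at 2.03 ± 0.26 (edgeR adjusted p = 7.03e-05). Neuron genes were lower, 5 of them past the threshold, with a median of -1.33 (camera adjusted p = 1.09e-05, adjusted p = 0.37 with an estimated correlation). Inflammatory cytokine and NF-kB genes gave -0.36 with 4 members lower over all genes and 7 when adjusted over the list alone (camera adjusted p = 3.81e-06, adjusted p = 0.233 with an estimated correlation). Il1a fell by 0.71 ± 0.14 (edgeR adjusted p = 0.0106) and Il1b fell by 0.66 ± 0.15 (0.022), and Per1 fell by 0.50 ± 0.08 (0.0011). The call of Il1b ended without HC NAIVE 1 (0.0709), PFC CUMS 1 (0.0802), PFC CUMS 2 (0.0550) or PFC NAIVE 2 (0.0611). Lpl, the lipoprotein lipase of activated microglia, was higher in the HC by 0.77 (edgeR adjusted p = 0.00267), and Cx3cr1 gave 0.02.

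Single genes differed between the regions by far more than any list. Qser1, a regulator of DNA methylation, had 0 counts in the 8 HC libraries and 2607 in the 7 PFC libraries, at least 1354-fold lower in the HC. Guca1a, a guanylate cyclase activator of the retina, had 1 count against 429. Both differences may come from counting rather than from expression, and both are reported as uncertain. The genes over 8-fold lower in the HC are weighed under the other observations. Hgs, an endosomal sorting protein, had 11377 counts in the HC and 3 in the PFC, and 97.2% of its exon bases are shared with a second identifier of the same symbol, so its level is uncertain. Rnaset2a, a lysosomal ribonuclease with 27.2% of its exon bases shared, fell by 7.67 ± 0.13, and Myl12b, a myosin light chain with 26.7% shared, fell by 4.95 ± 0.09. Other genes lower in the HC with shared exons were the glucuronyltransferase B4gat1 (85.3%), the transcription regulator Brms1 (79%) and the ribosomal protein Rps10 (20.6%), and all of these are reported as uncertain. With edgeR 500 genes were higher and 244 lower in the HC, 2766 had an unadjusted p under 0.05, and DESeq2 called 1173. The count of 744 was 292 without PFC CUMS 1, 411 without PFC CUMS 2, 393 without HC NAIVE 2 and 471 without HC CUMS_M 1.

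In the enrichment experiment (HC against PFC, n = 6 and 6) edgeR called 0 genes (smallest adjusted p = 1), 331 had an unadjusted p under 0.05, and DESeq2 called 0. The endothelial and mural list gave 0.49 (camera adjusted p = 6.18e-05, adjusted p = 0.946 with an estimated correlation), the oligodendrocyte list 0.39 (0.00271 and 0.946) and the astrocyte list 0.25 (0.00575 and 0.946). The choroid plexus level was 3.38 to 4.63 log2 CPM in HC EE, but -1.53, -0.92 and 2.16 in HC VEH, -1.46, 3.85 and 2.14 in PFC EE, and -1.55, 3.11 and 2.91 in PFC VEH.

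**Figure D5:**
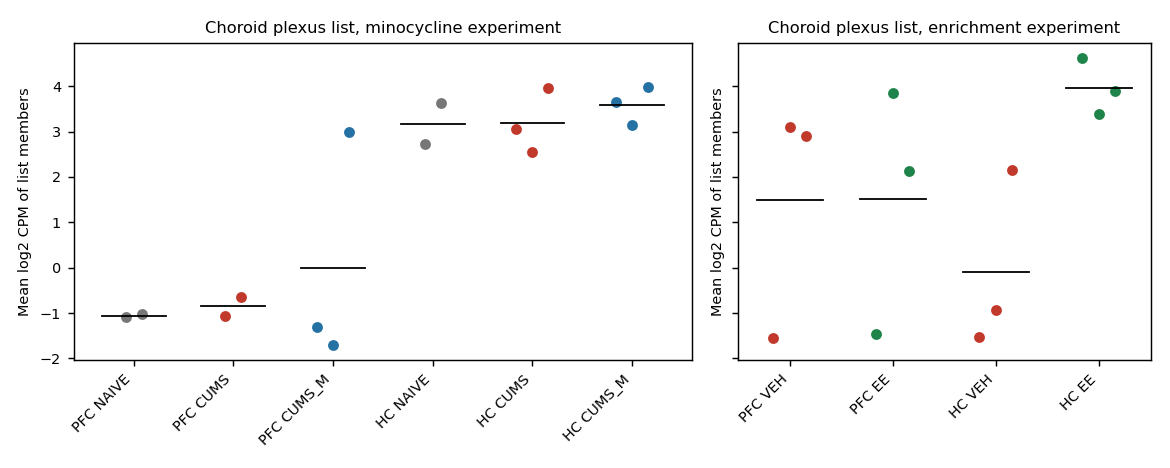
Mean log2 CPM of the choroid plexus and ependyma list (vertical axis) in each library of both experiments (horizontal axis, by group), with points for libraries and lines for group means. In the minocycline experiment the HC libraries start at 2.56 and the PFC libraries lie at or under -0.64 except PFC CUMS_M 3 at 3.001, while in the enrichment experiment both regions hold low and high libraries.

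Positions on GRCm38 (GENCODE M21 genes) of the main genes named were as follows. Aldh1l1 (ENSMUSG00000030088) lies on chromosome 6 at 90486427 to 90600203, Ntsr2 (ENSMUSG00000020591) on chromosome 12 at 16653382 to 16660227, and Ly6c1 (ENSMUSG00000079018) on chromosome 15 at 75044018 to 75048830. Cldn5 (ENSMUSG00000041378) lies on chromosome 16 at 18776847 to 18778262, Ptn (ENSMUSG00000029838) on chromosome 6 at 36714929 to 36810220, and Plxnb1 (ENSMUSG00000053646) on chromosome 9 at 109095389 to 109119917. Per1 (ENSMUSG00000020893) lies on chromosome 11 at 69095217 to 69109960, and Mfge8 (ENSMUSG00000030605) on chromosome 7 at 79133768 to 79149060. Hba-a1 (ENSMUSG00000069919) lies on chromosome 11 at 32283511 to 32284465, Tyro3 (ENSMUSG00000027298) on chromosome 2 at 119797733 to 119818104, Ttr (ENSMUSG00000061808) on chromosome 18 at 20665280 to 20674321, and Qser1 (ENSMUSG00000074994) on chromosome 2 at 104754795 to 104816760.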

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

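The tests of time of day, of dissociation and of a trimmed list were chosen only after the result was seen, and the gene lists and the splits of the samples were fixed before the data were examined.

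Per1, the clock gene that glucocorticoids induce directly, was lower in CUMS_M than in CUMS in the HC. In the PFC its change had the opposite sign but did not pass the threshold, so a rise there was not shown. Its log2 fold change in CUMS_M against CUMS was -1.01 ± 0.13 in the HC and 0.38 ± 0.14 in the PFC, and the tested difference was -1.39 (edgeR adjusted p = 0.0107). The glucocorticoid-responsive list to which it belongs differed by -0.32 between the regions (camera adjusted p = 3.6e-07, adjusted p = 0.00716 with an estimated correlation). Both were picked out because the difference between the regions itself passed its test. The Per1 difference missed the threshold without HC CUMS 3 (0.0575), HC CUMS_M 1 (0.0631), PFC CUMS 1 (0.197) or PFC CUMS 2 (0.151), and the list difference was not refitted without single libraries.

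The pattern weighed is that immediate early, NF-kB and glucocorticoid-responsive genes were lower in HC CUMS_M than in HC CUMS, with Per1 the only gene called. A different time of day of tissue collection was tested with 8 clock genes, whose median log2 fold change was -0.0483 (95% interval over the genes -0.294 to 0.0348). Of these 6 were below 0 and 0 passed the threshold. They showed no large common fall, but the interval leaves out the spread between libraries, so a smaller shift stays open. Activation of cells during dissociation and sorting stays open, since the deviations of libraries from their group means in immediate early and heat shock levels had r = 0.445 over 27 libraries (one-sided permutation p = 0.0087, Spearman 0.392 with p = 0.022, and r = 0.424 without the 2 farthest libraries), which is between the bounds set for the test. The deviations within a group sum to 0 and so depend on each other, which these permutation p-values ignore, so they are too small. An action of minocycline through glucocorticoid-responsive transcription stays open as well. The list without its members shared with the immediate early and NF-kB lists had a median of -0.34 (p = 0.000431 with an estimated correlation), but it keeps 16 of the 18 members and the same libraries, so it restates the pattern.

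For HC CUMS_M against CUMS edgeR called 1 gene in the real grouping, and 1 of the 10 splits of the 6 libraries gave as many, the highest other being 0. For the lists 15 were called, 3 of the 10 splits gave as many, and the highest other was 18. The 10 splits are too few for a share under 0.05.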

How the results depend on the processing

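The alternatives chosen only after the data were seen were the fits of only the libraries of a region, the fits without libraries that stood apart, the fit without genes that share exons, the block within the PFC, and the trimmed glucocorticoid-responsive list.

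With the size factors of DESeq2 every count of called genes stayed within 1.5 times of the reported one, at 118 for PFC CUMS against NAIVE and 748 for HC against PFC in the minocycline table. Of the alternative values of the lists 757 kept direction and side of the threshold, 257 fell short of it and 20 reversed. Of those of the named genes 2669 did so, 94 flipped sign without a call on either side, 662 fell short of the threshold and 7 passed it. Except where a sentence says otherwise, the cause was not tested.

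Counts of called genes rose without the filter on low counts, to 402 for PFC CUMS against NAIVE, 17 for HC CUMS against NAIVE, 170 for PFC CUMS_M against CUMS, 31 for HC CUMS_M against CUMS, 268 for PFC CUMS_M against NAIVE, 8 for HC CUMS_M against NAIVE, and 1191 for HC against PFC in the minocycline table. They were 57 and 37 for the region differences of CUMS against NAIVE and CUMS_M against CUMS, 19 for PFC EE, 278 for HC EE and 8 for the region difference of EE. The DESeq2 Wald test gave 348, 1, 85, 36, 143, 1 and 1173 for the same first 7 contrasts, 27 and 2 for those region differences, 17 for PFC EE and 441 for HC EE.

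With the replicate number as a replicate block 88 genes were called in PFC CUMS against NAIVE and 558 between regions in the minocycline table. The block gave 0 for PFC CUMS_M against CUMS, 3 for HC CUMS_M against CUMS, 3 for PFC CUMS_M against NAIVE, and 2 for the region difference of CUMS_M against CUMS. A replicate block within treatment gave 428 between the regions. In PFC EE against VEH, where the numbers met the bound for pairs, the replicate block and a replicate block within the PFC each gave 0 genes and ended none of the 11 list calls. Outside that comparison replicate numbers did not meet the bound. Pairs of libraries with equal number from different groups correlated, as deviations from their group means, with a median r of 0.00569 in the minocycline table (2 of 33 pairs over 0.1) and -0.0647 in the enrichment table (4 of 15). Single pairs were high there, with HC VEH 1 and PFC VEH 1 at 0.438, above every pair of PFC EE and VEH. For HC VEH and PFC VEH the pairs numbered 2 and 3 gave -0.0408 and 0.221.

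With the score of non-microglial markers as a covariate the counts were 2 for PFC CUMS against NAIVE, 1 for HC CUMS against NAIVE, 0 for PFC CUMS_M against CUMS, 5 for HC CUMS_M against CUMS, 40 for PFC CUMS_M against NAIVE, 235 between regions, 2 for the region difference of CUMS against NAIVE and 0 for that of CUMS_M against CUMS. The score turned the oligodendrocyte list to -0.20 in HC CUMS against NAIVE, 1.203 in PFC CUMS_M against CUMS and 0.27 in HC CUMS_M against CUMS. It ended the calls of the astrocyte list in PFC CUMS_M against CUMS (-0.11, camera adjusted p = 0.564) and of the endothelial list in PFC CUMS against NAIVE (0.80, 0.135), that of type I interferon genes in PFC CUMS_M against CUMS (-0.0202, 0.564), and that of cholesterol synthesis in HC EE against VEH (0.0312, 0.830). It turned immediate early genes to -0.48, cholesterol synthesis to 0.19 and neuron genes to 0.34 in PFC CUMS_M against CUMS. In HC EE against VEH it turned disease-associated microglia genes to -0.15, glycolysis to -0.10, endothelial genes to -0.20 and antigen presentation from 0.21 to 0.0035 with a test of the opposite sign. The score contains the members of those cell lists, so a loss or turn of the astrocyte, oligodendrocyte, neuron and endothelial lists follows in part from its construction.

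With only the groups compared the counts were 26 for PFC CUMS against NAIVE, 68 for PFC CUMS_M against CUMS, 0 for PFC CUMS_M against NAIVE, 1 for HC CUMS_M against NAIVE and 223 for HC EE against VEH. With only the libraries of the region they were 48, 5 and 2 for the same first 3 contrasts and 223 for HC EE. Without PFC NAIVE 1 and PFC CUMS_M 3 they were 32, 61 and 0 in the PFC, 1 for HC CUMS against NAIVE, 3 for HC CUMS_M against CUMS and 6 for the region difference of CUMS_M against CUMS, and the homeostatic list in PFC CUMS_M against NAIVE turned to 0.0360. Without the 3 enrichment libraries that stood apart (PFC VEH 1, PFC EE 1 and HC VEH 1) they were 1 for PFC EE and 153 for HC EE, and the ribosomal list in PFC EE had a median of -0.0321 with a test of the opposite sign. Without genes that share exons 667 genes were called between the regions.

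Leaving out each library in turn gave 13 to 540 genes for PFC CUMS against NAIVE, 0 to 1 for HC CUMS against NAIVE, 0 to 9 for PFC CUMS_M against CUMS, 0 to 5 for HC CUMS_M against CUMS, 0 to 610 for PFC CUMS_M against NAIVE, 0 to 1 for HC CUMS_M against NAIVE, and 292 to 983 between regions in the minocycline table. The ranges were 0 to 140 for the region difference of CUMS against NAIVE, 0 to 1 for that of CUMS_M against CUMS, 0 to 2 for PFC EE and 0 to 41 for HC EE. Immediate early genes in HC CUMS_M against NAIVE ran from -0.76 (without HC NAIVE 2) to 0.16 (without HC NAIVE 1). In HC CUMS against NAIVE ribosomal genes ran from -0.32 to 0.0688 and OXPHOS genes from -0.26 to 0.0250, and in HC CUMS_M against NAIVE from -0.34 to 0.0593 and from -0.22 to 0.0611, each reversed without HC NAIVE 2. Ribosomal genes ran from -0.0594 (without PFC CUMS 1) to 0.48 in PFC CUMS_M against CUMS. In PFC EE ribosomal genes ran from -0.69 to 0.19 and OXPHOS genes from -0.45 to 0.0287, both reversed without PFC VEH 1. Where this left a group with 1 library, that library is assumed to vary like the other groups.

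The correlation of the CUMS and minocycline effects was -0.330 in the PFC and -0.447 in the HC as reported. It was -0.411 and -0.701 over genes with a mean log2 CPM of 5 or more, -0.360 and -0.426 as Spearman's rho, -0.364 and -0.492 with the replicate block, and -0.493 to -0.228 and -0.569 to -0.306 over the leave-outs. The correlation of the minocycline and EE effects in the PFC was 0.00892 over genes with a mean of 5 or more and 0.0150 without PFC VEH 3, with leave-outs from -0.134 to 0.0150. In the HC it was 0.0199 with the replicate block, 0.143 without HC CUMS 3, 0.0712 without HC CUMS_M 2, 0.0259 without HC EE 1 and 0.0104 without HC VEH 1, with leave-outs from -0.130 to 0.143.

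The totals of 7.87 M to 15.3 M counts limit the genes of other cells in PFC NAIVE, where several had 0 counts and their rises are lower bounds.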

Other observations

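The tests of a lower microglial share, without PFC NAIVE 1, of exon sharing, of the region difference, of the choroid plexus, of the concordance of the treatments and of the splits that part equal numbers were chosen only after the result was seen, and the second marker sets, the thinning and the other splits were planned.

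Antigen presentation genes were higher in HC EE than in HC VEH by a median of 0.21 (camera adjusted p = 0.0038, adjusted p = 0.632 with an estimated correlation, camera 0.0604 without HC VEH 3, and 0.32 as the median without HC VEH 1). Ciita, the master regulator of MHC class II, gave 1.35 and the class II gene H2-Eb1 gave 1.11. The small heat shock protein Cryab, abundant in oligodendrocytes, was at 15.5 ± 4.69 against 3.53 ± 1.09 CPM (2.14, edgeR adjusted p = 0.0603), and Gfap, the astrocyte filament, gave 2.12 (0.0811). Mitochondrially encoded mRNAs gave -0.98 in HC EE (camera adjusted p = 0.00258, adjusted p = 0.583 with an estimated correlation) but -0.28 without HC VEH 3 (0.169).

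Type I interferon genes gave -0.18 in PFC CUMS_M against CUMS (camera adjusted p = 0.0138, adjusted p = 0.813 with an estimated correlation, and -0.0855 with camera 0.328 without PFC CUMS_M 2). Their median was -0.11 without PFC CUMS 1, -0.30 without PFC CUMS_M 3, and -0.0202 with the score of non-microglial markers as a covariate, which ended the call (0.564). Between the regions of the minocycline table Slc7a5, a large neutral amino acid transporter, was higher in the HC by 0.48 (edgeR adjusted p = 0.000426).

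The first pattern weighed is the rise of astrocyte and endothelial genes in PFC CUMS over PFC NAIVE, where Aldoc, abundant in astrocytes, reached 109 ± 10.3 CPM beside 7892 CPM of the microglial Cx3cr1. The oligodendrocyte, neutrophil and monocyte lists together did not rise like the astrocyte list. Their median was -0.560 (36 members, 95% interval over members -0.839 to -0.0927, against 1.98 to 2.99 for the astrocyte list). Neutrophils and monocytes are myeloid cells, which the CD11b sort can keep, and the oligodendrocyte list alone had a median of 0.14. The pooled median therefore cannot decide whether a lower share of microglia raised the genes of cells without CD11b. The smaller NAIVE libraries are argued against by a median of 2.65 for the astrocyte list after thinning to 7867323 counts, and PFC NAIVE 1 alone by a median of 2.37 without it. RNA of astrocytes and endothelial cells left in the CD11b sort remains a candidate source, since 0 genes of either list are in another list, and a second astrocyte set gave 2.45 (12 of 12 members above 0, 7 past the threshold) and a second endothelial set gave 1.63 (10 of 12, 0 past it). An effect of CUMS on these cells, or on what microglia take up from them, was not tested.

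The next pattern is the over 8-fold difference of single genes between the regions of the minocycline table, where for the 18 lower in the HC an annotation or counting rule that differed between the regions may be the source, since 11 shared exons with other genes (61.1%, one-sided Fisher exact p = 2.77e-08). Of the 138 genes higher in the HC, 9 shared exons on the same strand (6.52%, upper 95% limit 12.02%, and 7 of 103 without the genes high in PFC CUMS_M 3). Such overlap is argued against as the source for most of the 138, and stays open for those 9, among them Hgs. Overlap on the opposite strand was not counted and the strand setting is not stated, so another counting rule stays open for all 138. Choroid plexus tissue in the HC samples, which the CD11b sort should remove, remains a candidate source of part of the higher genes, since 8 of 8 HC libraries had a choroid plexus level above all PFC libraries but PFC CUMS_M 3, and 35 of the 156 genes were over 8-fold higher in that library.

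In each of the 12 enrichment libraries, whatever its region label, 14 to 18 of the 18 lower genes lay nearer the HC level of the minocycline table than its PFC level. The tables hold different numbers of identifiers (53412 and 55421) and may have been counted by different rules. Levels compared across them therefore cannot decide whether the brain regions differ in these genes. A difference between the brain regions stays open for the higher genes as well, whose median in the enrichment table (130 tested) was -0.0693 (95% interval -0.130 to 0.0273). That table called 0 genes between regions and its choroid plexus markers did not follow the region labels.

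For HC against PFC in the minocycline table edgeR called 744 genes. Of 100 splits 1, the real one, gave as many, and the highest other was 175, in a split that exchanged PFC CUMS_M 3 and HC CUMS_M 3. A random split is thus an unlikely source of the 744 calls, but the splits cannot tell brain region from a difference in processing between the regions. In the enrichment table edgeR called 0, 100 of 100 splits gave as many, and 1 split called 1614 (HC EE 1, HC VEH 2, HC VEH 3, PFC EE 2, PFC EE 3 and PFC VEH 3 against the rest). The libraries named had the lowest cytosolic ribosomal protein levels of that table (6.64 to 7.07 log2 CPM, against 7.11 to 8.21 in the rest). Choroid plexus levels were not parted by this split, with HC VEH 2 at -0.92 among the libraries named and HC EE 2 at 3.38 in the rest. The split thus follows a difference in composition between libraries. It gives no evidence on the region labels, and its cause was not tested. For the region difference of EE against VEH 0 genes were called, 100 of 100 splits gave as many, and the highest other was 89. Any split gives at least 0, so these 2 shares of 100 were fixed in advance and say nothing.

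For PFC EE against VEH edgeR called 0 genes, as did all 10 of the 10 splits (highest other 0), and 11 lists, which 8 of the 10 splits matched (highest other 26). Of the 4 splits that part all 3 pairs of equal number, 3 gave as many lists (highest other 12). For HC EE against VEH it called 0 genes, as did 10 of 10 splits (highest other 0), and 14 lists, which 3 of the 10 matched (highest other 17). The splits matched 0 genes by construction, and 10 are too few for a share under 0.05. The correlation of the minocycline and EE effects in the HC was matched in absolute value by 87 of 100 pairs of splits (highest other 0.330), so chance cannot be excluded.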
